A study of Homo sapiens with 6 samples.

How the data were processed

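RNA from PC-3/Mc and PC-3/S, sublines of the human prostate carcinoma cell line PC-3, was measured on 6 one-colour Affymetrix oligonucleotide arrays, 3 per line. Per the labels' protocols, cells were harvested before confluence, total RNA was isolated with a silica-column kit, and biotin-labelled target was made by the manufacturer's standard procedure. Each array was assigned to its line from its title, which also gives a biological replicate number from 1 to 3. The labels do not say whether replicates came from separate cultures or passages, so that p-values measure only the spread between these samples, which may be technical.

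The starting point was the table of processed log2 expression values that the authors deposited, with 54675 probe sets for each of the 6 arrays and no other sample columns. The software, the background correction and the normalization between arrays are not given in the sources used here. The scale was settled from the values: they ran from 2.59 to 14.45, and the highest equals a linear signal of 22358 if the base is 2 but 1883185 if the base is e, beyond the range of an array scanner. Values were not centred per gene, since none was below 0, and a one-colour array has no direction of ratio to settle. The method and target of the scaling between arrays stay unknown. The array medians were 5.00, 4.98 and 5.05 for PC-3/Mc replicates 1, 2 and 3, and 5.06, 5.09 and 5.02 for the PC-3/S replicates. These medians lay within 0.11 of each other, so the values entered the tests as deposited. Normalization between arrays makes each difference relative to the other probe sets of the array, and a shift of most transcripts in one direction would not be seen. The number of arrays limits the precision, with a median standard error of 0.092 on the log2 scale for the difference between lines.

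Probe sets were named through the platform annotation. Apart from 62 control probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 had none; only those with 1 symbol named a gene. Gene identifiers of 41037 probe sets were found in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. That table was used for names and for the order of neighbouring genes, and no coordinates are printed because the build behind the array annotation is not given in the sources used here. Each of the 19775 genes was represented by its probe set with the highest mean over the 6 arrays; 10523 genes had more than 1 probe set to choose from. The median of all genes was 5.98, and a gene below it in both lines is called dim. Detection calls were not used here, so the highest reading of CTNNA1, a gene known to be deleted in PC-3, served as a rough floor (5.18), chosen after the values were seen. Where the dimmer line's mean lay at or under it, the fold is a lower bound: the brighter line's mean against the dimmer line's mean with each array raised to the floor.

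Differences are PC-3/Mc minus PC-3/S on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates) over all 19775 genes with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and a further count asked for an absolute log2 difference of at least 1. The comparison, the lists and the genes to be named were fixed before the data were examined. The named genes are the 12 largest differences in each direction among called genes whose arrays did not overlap between the lines and whose mean in the higher line reached the median of all genes, up to 4 called members of at least 2-fold difference per direction in each list under the same limit on level, and a set of anchor genes given whatever their values. XIST and Y-linked genes were left out of the naming. POU5F1, an anchor, has no probe set with a single symbol and is not analysed here.

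The 23 lists held 808 entries, 726 of them measured. They cover epithelial genes, mesenchymal and matrix genes, transcription factors of the epithelial-mesenchymal transition (EMT), pluripotency factors, tumor-initiating cell markers, MYC targets, cell cycle genes and inhibitors, the TGF-beta and BMP, WNT and Notch pathways, proteases, integrins, interferon response, antigen presentation, cytokines, hypoxia and glycolysis, lipid synthesis, androgen receptor and luminal genes, basal genes, neural genes, cancer-testis antigens and ribosomal proteins. A further 7 marker lists covered other cell types. Camera in limma compared each list with all other genes at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists. It was run again with the correlation estimated for each list. Fry, a self-contained test, asked whether a list moved on balance one way, and its mixed form whether members changed in either direction. Neither form compares a list with other genes. Values per array, such as the 3' to 5' difference of control probe sets, were compared with an exact permutation test, whose smallest two-sided p with 3 against 3 arrays is 0.1.

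The procedure was tested on simulated data of 19775 genes with 200 changed. It recovered 62.7% of changes of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold, with 10 false calls among 180. A list shifted by 0.5 was called, and 0 of 22 unchanged lists were. Simulated genes varied independently, so the list result does not cover correlated members. Among the lists called in the data, the estimated correlation ran from 0.017 (epithelial) to 0.243 (interferon). Far fewer genes were changed than the 9083 called in the data. Alternatives were quantile normalization of the deposited values, arrays centred on their medians, genes below the 40th percentile left out, the mean of a gene's probe sets, probe sets ending in _x_at or _s_at left out (these can bind related transcripts), all probe sets tested, a trended robust prior, a replicate block, each array left out in turn, an estimated correlation and fry for lists, and other control probe sets for RNA quality. A planned change of pseudocount was not run because the values were already on a log scale.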

Results

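Expression was compared between PC-3/Mc and PC-3/S, 2 sublines of PC-3, an established prostate carcinoma line that came from a bone metastasis. The series concerns how the epithelial-mesenchymal transition affects tumor-initiating attributes. The single comparison asks which transcripts separate the 2 lines. Each line was measured on 3 arrays, and unless another n is named every mean ± SD and every difference ± SE below rests on n = 3 arrays per line. Differences are PC-3/Mc minus PC-3/S on the log2 scale, and adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment.

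The 6 arrays were similar in brightness, with medians between 4.98 and 5.09. Correlations across probe sets were 0.995 to 0.997 between arrays of the same line and 0.949 to 0.952 between lines. The first principal component separated the lines and held 88.7% of the variance, against 4.47% for the second. No 2 arrays held identical values. The 3' minus 5' difference of the GAPDH control probe sets, a sign of RNA degradation when it is large, was -0.033 ± 0.066 in PC-3/Mc and 0.041 ± 0.031 in PC-3/S (exact permutation p = 0.3). For ACTB it was 0.055 ± 0.121 and 0.129 ± 0.059 (exact permutation p = 0.6). Hybridisation control spikes averaged 10.97 ± 0.13 and 10.92 ± 0.02 (exact permutation p = 0.9). The smallest p this design allows is 0.1, so these tests could not pass a threshold of 0.05.

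The lines differed widely. Of 19775 genes, 4585 were higher and 4498 lower in PC-3/Mc, together 45.9% of those tested, and 2266 (11.5%) differed at least 2-fold, 1163 higher and 1103 lower. At least 8-fold differences were found for 92 genes higher and 118 lower. Detection calls were not used here, and CTNNA1, a gene known to be deleted in PC-3 and chosen after its values were seen, read between 3.51 and 5.18 on its 5 probe sets. Readings of up to 5.18 are therefore treated as possibly background: where the dimmer line lay there, folds are given as lower bounds against that reading, and log2 differences, given as measured, have no firm order among such genes. This holds for 612 of the 2266 genes, 41 of them in both lines, and for 162 of the 210 of at least 8-fold. UCHL1, a ubiquitin hydrolase abundant in neurons, was at 12.89 ± 0.07 in PC-3/Mc against 5.02 ± 0.20, at least 207-fold higher (adjusted p = 7.9e-12). CD24, a surface glycoprotein of many epithelial tumors, was at least 69.6-fold higher, and DSP, which encodes the desmosomal protein desmoplakin, at least 37.3-fold. BCAT1, the cytosolic branched-chain aminotransferase, differed by 6.10 ± 0.10 and the neuropeptide gene GAL by 5.74 ± 0.08. Also among the 12 largest measured differences were UTS2B (5.88), ZFPM2 (5.84), DNAH5 (5.62), EPCAM (5.43), MAGEA10 (5.40), the interleukin receptor gene IL13RA2 (5.34) and PPP2R2C (5.33).

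Lower in PC-3/Mc was INHBA, which encodes a subunit of activin A, at 4.52 ± 0.18 against 12.59 ± 0.07 in PC-3/S, a difference of at least 170-fold (adjusted p = 7.7e-12). INHBB, which encodes another activin subunit, differed by -6.16 ± 0.07. IGFBP3, a binding protein of insulin-like growth factors, was 147-fold lower, and the matrix gene FN1 (fibronectin) 78.2-fold lower. CXCL8, the neutrophil chemoattractant interleukin-8, was at 13.22 ± 0.05 in PC-3/S and 7.63 ± 0.05 in PC-3/Mc. The others of the 12 largest measured differences were COX7B2 (-6.59), BASP1 (-6.46), the survival gene BCL2A1 (-6.44), the proteoglycan gene SRGN (-6.41), ARMCX3 (-6.04), TSPYL5 (-5.72) and the interleukin-33 receptor gene IL1RL1 (-5.67). The arrays of the 2 lines did not overlap for 10503 genes (53.1%), where chance gives 10%. The median difference over all genes was -0.03.

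**Figure D1:**
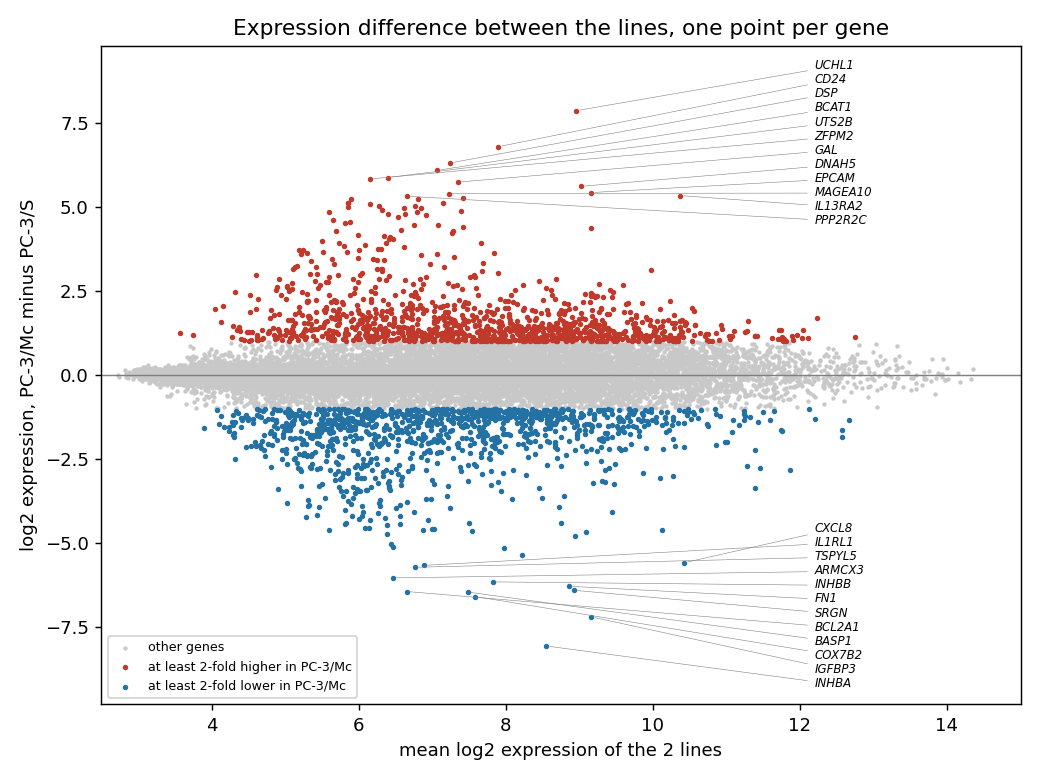
Difference between lines (PC-3/Mc minus PC-3/S, log2) against the mean log2 expression of both lines, one point per gene, from 3 arrays per line. The 1163 red and 1103 blue points are called genes at least 2-fold higher or lower in PC-3/Mc, and the labelled genes run, as measured, from INHBA at -8.07 to UCHL1 at 7.87.

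Genes of epithelial junctions and identity were shifted towards PC-3/Mc. Of 47 measured members 25 were higher, 7 lower and 15 not called (25 and 8 adjusted over the list alone), with a median difference of 0.30. E-cadherin (CDH1), the adherens junction protein, was at 7.67 ± 0.19 in PC-3/Mc, at least 5.65-fold above PC-3/S; its other probe set read under 5.18 in both lines. The adhesion molecule EPCAM was 43.3-fold higher, the epithelial splicing regulator ESRP1 at least 9.63-fold, and the transcription factor EHF at least 19.2-fold, each measured with an SE of at most 0.13 on the log2 scale. Against this direction ran KRT7 (-1.54 ± 0.10), a simple-epithelium keratin, and JUP (-1.12 ± 0.09), which encodes plakoglobin. The KRT7 call was lost when probe sets ending in _x_at or _s_at were left out (-0.18, adjusted p = 0.23). Camera gave an adjusted p of 4.3e-05 for the list, and the call was lost at adjusted p = 0.155 with an estimated correlation.

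Mesenchymal and matrix genes were shifted the other way, with 28 of 50 lower in PC-3/Mc, 11 higher and 11 not called (28 and 12 adjusted over the list alone) and a median of -0.36. After FN1, the largest measured differences were those of CCN1, a matricellular growth regulator (-4.61 ± 0.09), SPARC, a collagen-binding glycoprotein (-4.41 ± 0.08), and COL6A3 (-4.09 ± 0.09). Not all matrix genes followed. COL1A2 was at least 9.90-fold higher in PC-3/Mc, and COL8A1 (2.21 ± 0.13), NID2 (1.89 ± 0.10) and LUM (1.81 ± 0.20) were higher as well. PC-3/S read under 5.18 for each of these, and the lower bound for LUM was 1.82-fold. Vimentin (VIM), the intermediate filament of mesenchymal cells, was at 13.08 ± 0.07 and 13.44 ± 0.03, lower in PC-3/Mc by a difference of -0.36 (adjusted p = 0.0026). N-cadherin (CDH2) was at 8.01 ± 0.13 and 7.82 ± 0.06 and did not pass the test (adjusted p = 0.12). The camera test of the list had an adjusted p of 0.00056 for the list, and adjusted p = 0.201 with an estimated correlation. With probe sets ending in _x_at or _s_at left out, the list fell short as well (adjusted p = 0.0952), LUM (0.02, adjusted p = 0.94) and FN1 (0.18, adjusted p = 0.33) were left with probe sets under 5.18 in both lines and without a call, while the 4 brightest FN1 probe sets differed by -6.29 to -7.16.

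Transcription factors of the transition gave 9 of 20 members lower in PC-3/Mc, 3 higher and 8 not called, the same counts adjusted over the list alone. RUNX2, the osteoblast regulator, was at least 5.07-fold lower, and TWIST2 differed by -1.65 ± 0.09 as measured (at least 1.82-fold). ETS1 differed by -1.76 ± 0.10 and the E-cadherin repressor ZEB1 by -1.27 ± 0.12. Slug (SNAI2), bright in both lines, differed by -0.97 ± 0.09 and TWIST1 by -0.47 ± 0.10. Snail (SNAI1) was higher in PC-3/Mc (0.57 ± 0.11) but dim in both lines at 5.36 and 4.79; FOXQ1 (0.58) and TCF4 (0.46), chosen after their values were seen, completed the 3. ZEB2 was dim at 4.44 ± 0.08 and 4.49 ± 0.09 and was not called (adjusted p = 0.64). The list did not pass camera (median -0.17, adjusted p = 0.054; adjusted p = 0.361 with an estimated correlation). Without PC-3/Mc replicate 1 or PC-3/S replicate 2 it passed, at adjusted p = 0.0426 and 0.0440.

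**Figure D2:**
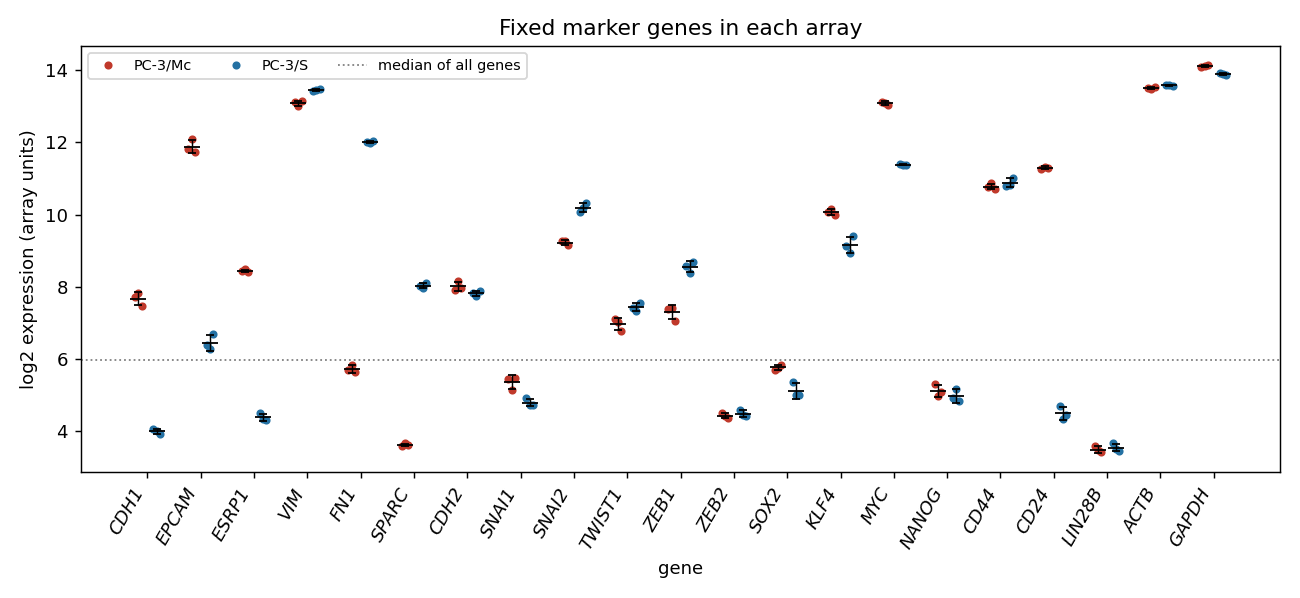
Log2 expression of the anchor genes fixed beforehand, each point 1 array, red for PC-3/Mc and blue for PC-3/S, with the mean and SD of 3 arrays as bars and the median of all genes (5.98) as a dotted line. EPCAM stood at 11.88 against 6.44 and FN1 at 5.72 against 12.01, while VIM lay at 13.08 and 13.44.

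Among pluripotency and reprogramming factors, MYC was higher in PC-3/Mc at 13.08 ± 0.05 against 11.38 ± 0.01, or 3.25-fold. KLF4 (0.92 ± 0.11), the DNA methyltransferase gene DNMT3B (1.38 ± 0.08) and ID1 (1.06 ± 0.09) were higher too. SOX2 was called higher (0.66 ± 0.11) but dim in both lines, at 5.77 and 5.12; another of its 4 probe sets, also dim, differed by 1.86. NANOG (0.15 ± 0.12, adjusted p = 0.35) and LIN28B (-0.05 ± 0.09, adjusted p = 0.68) were dim and not called. Of 32 measured members 9 were higher, 3 lower and 20 not called, unchanged when adjusted over the list alone. The 3 were TBX3 (-2.69 ± 0.09) and, chosen after their values were seen, TERF1 (-0.92) and SALL4 (-0.23). The list did not pass camera (median 0.07, adjusted p = 0.209; adjusted p = 0.361 with an estimated correlation).

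Markers used for tumor-initiating and stem cells gave 9 higher, 6 lower and 12 not called of 27, with the same counts adjusted over the list alone. Beside CD24, the R-spondin receptor genes LGR5 (5.13 ± 0.10) and LGR4 (2.65 ± 0.14) and the retinaldehyde dehydrogenase gene ALDH1A2 (4.81 ± 0.10) were higher in PC-3/Mc. LGR4 was not called when probe sets ending in _x_at or _s_at were left out (0.22, adjusted p = 0.12), on a probe set under 5.18 in both lines. The hyaluronan receptor CD44 was at 10.78 ± 0.08 and 10.88 ± 0.12 and not called (adjusted p = 0.37); of its 13 probe sets, 2 dimmer ones were higher in PC-3/Mc by 0.80 and 0.71. The list did not pass camera (adjusted p = 0.209; adjusted p = 0.426 with an estimated correlation). Its median was -0.01 while its mean (0.80) and camera pointed to PC-3/Mc.

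In the list of MYC targets and ribosome biogenesis, 30 of 37 members were higher in PC-3/Mc, 6 were not called and 1 was lower (31 and 1 adjusted over the list alone), with a median of 0.65. PA2G4, a growth-associated RNA-binding protein, differed by 1.67 ± 0.09, the mitochondrial chaperonin gene HSPE1 by 1.36 ± 0.10, the cyclin D kinase gene CDK4 by 1.31 ± 0.07 and the nucleolar gene RRP9 by 1.30 ± 0.08. The single lower member was ODC1 (-0.56), the polyamine synthesis enzyme, chosen after its value was seen. Against all other genes, camera gave an adjusted p of 5.9e-09, and adjusted p = 0.155 with an estimated correlation. Cell cycle and mitosis genes were higher for 49 of 56 members, with 3 lower and 4 not called, the same adjusted over the list alone, and a median of 0.80. Cyclin A2 (CCNA2, 1.86 ± 0.08), the replicative helicase gene MCM2 (1.62 ± 0.08), and the mitotic kinase genes PLK1 (1.60 ± 0.14) and TTK (1.57 ± 0.09) led the list. The 3 lower were CCND1 (-0.74), CCNE2 (-0.51) and NUSAP1 (-0.37), and the 4 uncalled GINS1, E2F1, MCM4 and CDC25C, all chosen after their values were seen. For the whole list the adjusted p of camera was 2.1e-14, and adjusted p = 0.155 with an estimated correlation.

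Cell cycle inhibitors went both ways, 4 higher, 6 lower and 3 not called of 13, unchanged adjusted over the list alone. CDKN1B (p27) was 3.03-fold higher in PC-3/Mc, while CDKN2B (-1.05 ± 0.13) and GADD45B (-2.07 ± 0.09) were lower. GADD45B had no call once probe sets ending in _x_at or _s_at were left out (-0.21, adjusted p = 0.11). The probe set then used was dim, at 5.18 in PC-3/Mc and 5.39 in PC-3/S. The other higher members, chosen after their values were seen, were CDKN2A (0.66), CDKN1A (0.46) and RBL1 (0.46), and those not called RB1, BTG1 and RBL2. Camera gave an adjusted p of 0.661, and adjusted p = 0.912 with an estimated correlation. Ribosomal protein genes served as a reference of steady transcripts. Of 24 members 3 were higher, 3 lower and 18 not called, also adjusted over the list alone; the 6, chosen after their values were seen, were RPLP2 (0.37), RPS9 (0.26), RPS6 (0.24), RPL8 (-0.29), RPS15 (-0.35) and RPL30 (-0.42). Their median of -0.04 turned to 0.01 when arrays were centred on their medians, and camera gave an adjusted p of 0.950 (adjusted p = 0.973 with an estimated correlation). ACTB was at 13.50 ± 0.02 and 13.58 ± 0.02 and not called (-0.07, adjusted p = 0.46). GAPDH was higher by 0.22 ± 0.07 (adjusted p = 0.028), a call that was lost whichever array was left out (adjusted p = 0.0513 to 0.0875); both genes kept their signs when the arrays were quantile-normalized or centred.

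In the TGF-beta and BMP list, 21 of 39 members were lower in PC-3/Mc, 10 higher and 8 not called (22 and 10 adjusted over the list alone), with a median of -0.42. Besides the activin genes INHBA and INHBB, the ligand gene TGFB2 (-2.29 ± 0.10) and the activin antagonist FST (-1.84 ± 0.08) were lower. Among members higher in PC-3/Mc were the signal transducer SMAD9 (3.23 ± 0.13), the ligands BMP6 (2.17 ± 0.08) and BMP2 (2.08 ± 0.13) and the BMP antagonist NOG (2.13 ± 0.15). The camera test of the list had an adjusted p of 0.031, and adjusted p = 0.361 with an estimated correlation. The call was also lost without genes below the 40th percentile of mean level (adjusted p = 0.0665), without probe sets ending in _x_at or _s_at (adjusted p = 0.114), without PC-3/Mc replicate 3 (adjusted p = 0.0780) and without PC-3/S replicate 3 (adjusted p = 0.0505).

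WNT pathway genes split into 9 higher, 11 lower and 14 not called of 34 (10 and 12 adjusted over the list alone). The receptor gene FZD7 was at least 2.23-fold higher in PC-3/Mc, and the ligase RNF43 (1.87 ± 0.12), the ligand WNT10B (1.86 ± 0.08) and the effector TCF7L2 (1.36 ± 0.11) were higher as well. TCF7L1 (-2.12 ± 0.10) and the non-canonical ligand WNT5A (-1.75 ± 0.10) were lower. Against all other genes, camera gave an adjusted p of 0.950 (adjusted p = 0.960 with an estimated correlation); median (-0.10) and camera pointed to PC-3/S and the mean (0.07) to PC-3/Mc. Of the Notch ligand genes, JAG2 was higher (2.40 ± 0.08) and JAG1 lower (-3.14 ± 0.10). The target gene HEY1 was 8.69-fold higher at 11.53 ± 0.09, and NRARP (1.73 ± 0.10) and LFNG (1.25 ± 0.08) were higher, while DTX3 (-1.64 ± 0.08), MAML2 (-1.43 ± 0.08) and HES2 (-1.07 ± 0.08) were lower. Of 27 members 9 were higher, 8 lower and 10 not called, likewise adjusted over the list alone. For the whole list the adjusted p of camera was 0.985 (adjusted p = 0.989 with an estimated correlation), the median (-0.05) pointing to PC-3/S and the mean (0.04) and camera to PC-3/Mc.

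Extracellular proteases and inhibitors numbered 10 higher, 10 lower and 22 not called of 42, with the same counts adjusted over the list alone. The epithelial serpin SERPINB5 (maspin, 2.53 ± 0.08), the collagenase MMP1 (2.01 ± 0.15) and SERPINE2 (1.60 ± 0.08) were higher in PC-3/Mc. ADAM12 (-2.33 ± 0.08), ADAMTS1 (-2.19 ± 0.08), the inhibitor TFPI2 (-2.09 ± 0.08) and urokinase, PLAU (-1.68 ± 0.07), were lower. Camera gave an adjusted p of 0.661 for a median of -0.11 (adjusted p = 0.701 with an estimated correlation). Integrins gave 6 higher, 6 lower and 7 not called of 19, also adjusted over the list alone. The pair that forms the hemidesmosomal laminin receptor, ITGB4 (1.89 ± 0.11) and ITGA6 (1.18 ± 0.08), was higher in PC-3/Mc, and ITGB4 had no call without probe sets ending in _x_at or _s_at (0.10, adjusted p = 0.58), again on a probe set under 5.18 in both lines. The collagen receptor gene ITGA1 was at least 4.66-fold lower, and ITGA3 (-1.20 ± 0.09) and ITGA10 (-1.07 ± 0.11 as measured, at least 1.79-fold) were lower. The camera test of the list had an adjusted p of 0.811 for a median of -0.12 (adjusted p = 0.857 with an estimated correlation).

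Interferon response genes were lower in PC-3/Mc for 35 of 44 members, 27 of them at least 2-fold, with 3 higher and 6 not called (36 and 3 adjusted over the list alone) and a median of -1.65. The antiviral GTPase gene MX1 was at 4.37 ± 0.20 against 8.18 ± 0.29, at least 8.05-fold lower. IFITM1 (-3.79 ± 0.16), IFIT2 (-3.24 ± 0.09) and the ISG15-conjugating enzyme gene UBE2L6 (-3.16 ± 0.09) were lower alike. The 3 higher, chosen after their values were seen, were PARP9 (0.84), OAS1 (0.54) and HERC5 (0.37). Against all other genes, camera gave an adjusted p of 3.4e-12, and adjusted p = 0.201 with an estimated correlation. Antigen presentation genes were lower for 12 of 21 members, with 8 not called and 1 higher, the same adjusted over the list alone, and a median of -0.42. The immunoproteasome subunit PSMB9 (-3.74 ± 0.11), the peptide transporter TAP1 (-2.50 ± 0.08), PSMB8 (-2.30 ± 0.08) and the class I gene HLA-C (-1.83 ± 0.07) led. The higher member was PSMB10 (0.70), chosen after its value was seen. For the whole list the adjusted p of camera was 0.00044, adjusted p = 0.185 with an estimated correlation and adjusted p = 0.42 without probe sets ending in _x_at or _s_at; transcripts of the class I genes are similar, so single class I genes are uncertain.

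Cytokine and chemokine genes were lower in PC-3/Mc for 24 of 34 members, 9 were not called and 1, the transmembrane chemokine CXCL16 (1.67 ± 0.10), was higher (25 and 1 adjusted over the list alone), with a median of -1.43. CXCL8 was followed by the related chemokine CXCL6, lower by 25.2-fold, leukemia inhibitory factor, LIF (-3.59 ± 0.08), and IL24 (-3.39 ± 0.13). Camera gave an adjusted p of 3.5e-10, and adjusted p = 0.155 with an estimated correlation. Leukocyte markers, given here because white blood cells express many genes of these lists, had a median difference of -0.08 in the same arrays, with 3 of 16 lower and 0 higher, and the highest reading in PC-3/S was 6.78 ± 0.05 for LCP1.

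Hypoxia and glycolysis genes were higher for 22 of 33 members, lower for 6 and not called for 5, as they were adjusted over the list alone, with a median of 0.45. Carbonic anhydrase CA12 (2.37 ± 0.09), adrenomedullin, ADM (2.01 ± 0.08), the phosphofructokinase gene PFKP (1.89 ± 0.09) and the MAX partner MXI1 (1.88 ± 0.08) were highest above PC-3/S, and ALDOC (-1.29 ± 0.08) farthest below. The 5 uncalled, chosen after their values were seen, were PFKFB4, ANKRD37, SLC2A3, PKM and NDRG1. The camera test of the list had an adjusted p of 0.00068, and adjusted p = 0.361 with an estimated correlation. After subtraction of the median difference of neighbouring genes along the chromosomes, over the 31 members placed among bright neighbours, the median fell from 0.45 to 0.21 (SD over members 0.88 and 0.79) and the adjusted p moved from 0.0448 to 0.165. In lipid synthesis ELOVL6 (2.12 ± 0.08) and SCD (1.23 ± 0.08) were higher, while TM7SF2 (-1.73 ± 0.10), HMGCS1 (-1.41 ± 0.12), INSIG1 (-1.39 ± 0.12) and LSS (-1.15 ± 0.07) were lower. The list gave 7 higher, 13 lower and 6 not called of 26 (8 and 13 adjusted over the list alone), and camera an adjusted p of 0.444 for a median of -0.19 (adjusted p = 0.674 with an estimated correlation).

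Androgen receptor and luminal genes gave 5 higher, 6 lower and 11 not called of 22, also adjusted over the list alone. FKBP5, a steroid receptor chaperone, differed by 2.81 ± 0.09 and the pioneer factor FOXA1 by 1.69 ± 0.09, while PMEPA1 (-3.11 ± 0.14), a gene induced by androgen and TGF-beta, and SPDEF (-1.30 ± 0.09) were lower. The other 3 higher, chosen after their values were seen, were HOXB13 (0.76), ABCC4 (0.59) and SLC45A3 (0.46). Against all other genes, camera gave an adjusted p of 0.950 for a median of -0.05 (adjusted p = 0.955 with an estimated correlation). Basal keratinocyte genes gave 7 higher, 6 lower and 14 not called of 27, unchanged adjusted over the list alone. The connexin gene GJB2 (2.75 ± 0.11), DSC3 (1.61 ± 0.10), SFN (1.33 ± 0.08) and PI3 (1.10 ± 0.08) were higher and the laminin gene LAMB3 (-2.20 ± 0.08) lower. For the whole list the adjusted p of camera was 0.950 (adjusted p = 0.955 with an estimated correlation), the median (-0.03) pointing to PC-3/S and the mean (0.08) and camera to PC-3/Mc.

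Neural genes, a list that held UCHL1, gave 6 higher, 3 lower and 22 not called of 31, the same adjusted over the list alone. Neurotensin, NTS (at least 17.3-fold), NRCAM (1.70 ± 0.10) and neurofilament light chain, NEFL (1.11 ± 0.09), were higher. The 3 lower were SCG5 (-1.41 ± 0.08) and, chosen after their values were seen, MAPT (-0.44) and SYT1 (-0.37). Camera gave an adjusted p of 0.447 for a median of 0.01 (adjusted p = 0.784 with an estimated correlation). Of 27 cancer-testis antigen genes 7 were higher, 6 lower and 14 not called, also adjusted over the list alone, and 5 and 4 of these were at least 2-fold higher and lower. MAGEA10 (at least 26.8-fold), CTAG2 (at least 29.4-fold) and MAGEC2 (4.45 as measured) were higher and MAGEA12 less so (1.13 ± 0.08), while PRAME (-2.88 ± 0.18), MAGEA11 (-2.34 ± 0.11), PAGE5 (-1.88 ± 0.10) and MAGED1 (-1.07 ± 0.07) were lower. Members of these families resemble each other, so single members are uncertain, and MAGEC2 had no call when probe sets ending in _x_at or _s_at were left out (-0.15, adjusted p = 0.39), which left one under 5.18 in both lines. The camera test of the list had an adjusted p of 0.574 for a median of 0.03 (adjusted p = 0.674 with an estimated correlation).

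Of the 23 lists, 9 passed camera at the preset correlation, 4 shifted to PC-3/Mc and 5 to PC-3/S. With an estimated correlation 0 passed (smallest adjusted p = 0.155), although 5 had an unadjusted p under 0.05. The epithelial list had an estimated correlation of 0.017, near the preset 0.01. Its unadjusted camera p still went from 9.5e-06 to 0.016. The loss of that call can therefore not be put down to correlated members alone. What else differs between the 2 settings was not tested. Fry found a balance of one direction in 17 lists and its mixed form a change in either direction in 23 (largest adjusted p = 1.1e-05). The shared direction of a list rests on 6 arrays, and the other 9 divisions of these arrays into 3 and 3 gave 4 to 7 lists at the preset correlation. Those divisions mix the lines and keep part of the line difference, so their list counts are not a chance level.

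**Figure D3:**
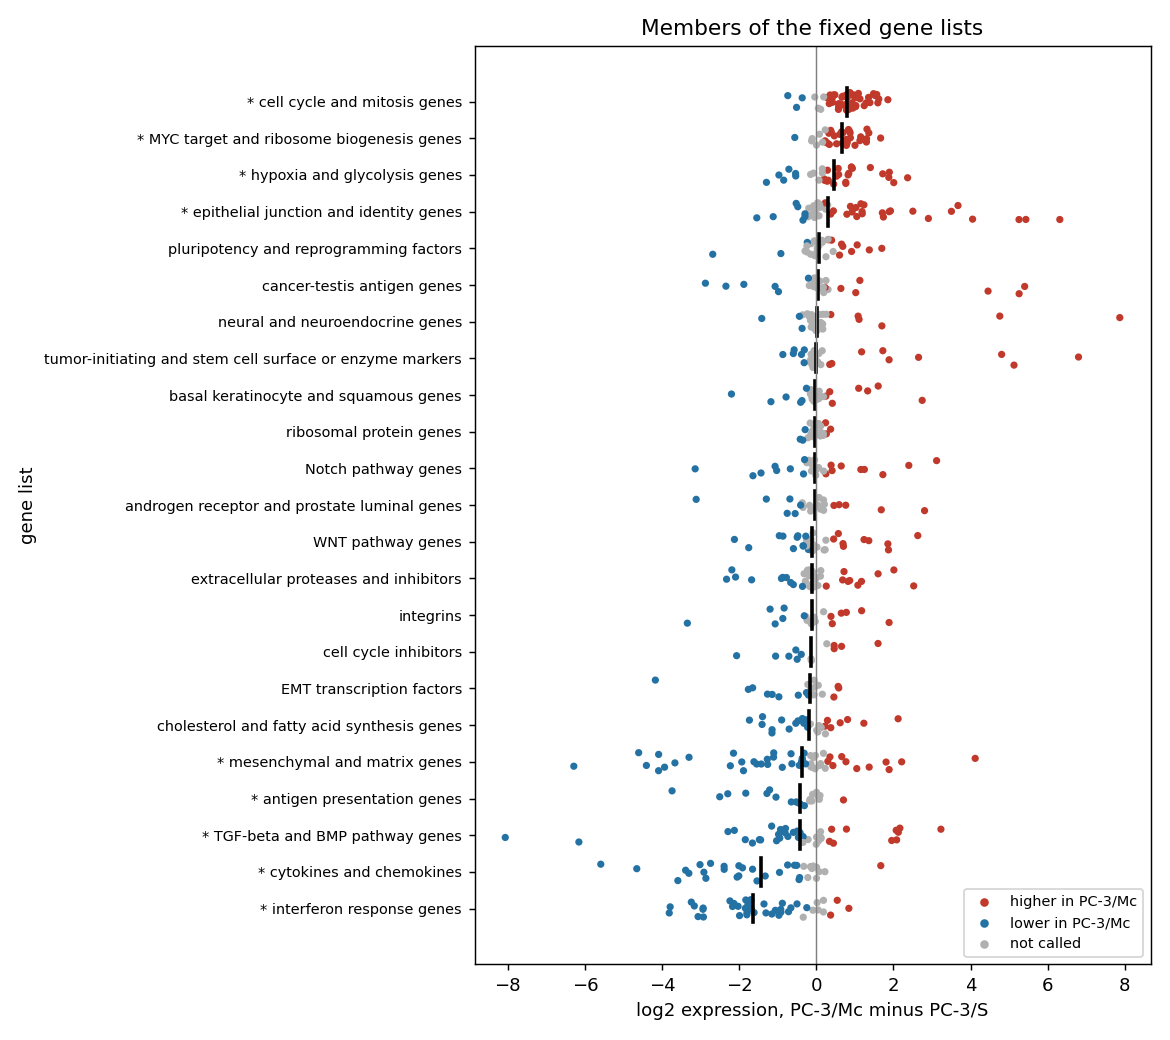
Difference between lines (PC-3/Mc minus PC-3/S, log2) for the measured members of the 23 lists, red higher, blue lower and grey not called, with a black bar at each list's median and an asterisk at the 9 lists that passed camera at the preset correlation, of which 0 passed with an estimated one. Medians ran from -1.65 for interferon response to 0.80 for cell cycle genes.

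Markers of other cell types were mostly dim. Of 14 fibroblast markers, 11 of them also in other lists, 4 were higher and 4 lower in PC-3/Mc (median 0.08); chosen after their values were seen, these were COL1A2, LUM, PDGFRB (0.35) and OGN (0.26) against COL3A1 (-1.93), TWIST1, DCN (-0.44) and COL1A1 (-0.28). The 3 lower leukocyte markers were LCP1 (-0.79), CD79A (-0.38) and ITGAM (-0.30), again chosen after their values were seen. Endothelial markers held 1 higher of 10, PECAM1 (0.60), and 1 lower, KDR (-2.17), chosen likewise, with a median of -0.13. Of 8 measured markers of androgen-responsive prostate lines, SLC45A3 (0.46) was higher and TMPRSS2 (-0.41) lower, with a median of -0.15. Among 6 melanocyte markers MITF (0.73) was higher and TYRP1 (-0.51) lower, with a median of -0.07; these 4 genes, too, were chosen after their values were seen. None of 11 hepatocyte markers (median -0.02) and none of 5 neuroendocrine markers (median -0.07) was called.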

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

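Alternatives were planned before the values were seen, and the cause was not tested for any result that did not hold. With all probe sets tested, 10033 were higher and 9549 lower, 2409 and 2152 of them at least 2-fold, against 4585, 4498, 1163 and 1103 genes. Leaving out 1 array gave 4146 to 4647 genes higher and 3829 to 4845 lower. A replicate block gave 4184 genes higher in PC-3/Mc and 3906 genes lower in PC-3/Mc, with the counts at least 2-fold unchanged, and GAPDH lost its call (adjusted p = 0.0771) with its difference still 0.22; the pairing check found 0 of 3 arrays closest to the same replicate number in the other line. With an estimated correlation all 9 list calls were lost: epithelial, MYC target, cell cycle and cytokine (adjusted p = 0.155 each), antigen presentation (0.185), mesenchymal and interferon (0.201 each), hypoxia and TGF-beta/BMP (0.361 each). TGF-beta/BMP also fell short without genes under the 40th percentile (0.0665) or without _x_at and _s_at probe sets (0.114) and ranged from 0.0176 to 0.0780 with 1 array left out; without those probe sets the mesenchymal (0.0952) and antigen presentation (0.42) calls ended. EMT transcription factors passed with quantile normalization (0.0463), centred arrays (0.0483) and fry (6.3e-05), and ranged from 0.0426 to 0.0834 with 1 array left out. Fry, which asks another question, called pluripotency (0.00091), tumor-initiating markers (2.1e-05), proteases (0.0093), integrins (0.0045), lipid synthesis (0.0093), neural (0.00060) and cancer-testis genes (0.00023). Direction turned, without a call, for WNT (quantile 0.991, no _x_at and _s_at 0.936, fry 0.091), Notch (centred 0.978, genes under the 40th percentile left out 0.753, mean of probe sets 0.779, without PC-3/Mc replicate 3 0.942, of a range to 0.983 with 1 array left out), ribosomal (centred 0.951, without PC-3/Mc replicate 3 0.942 and without PC-3/S replicate 3 0.978, of a range from 0.926 to 0.981), proteases (no _x_at and _s_at 0.803), androgen receptor (0.911; fry 0.153) and cancer-testis genes (0.802). Of the 2266 genes at least 2-fold different, 1577 stayed so with the mean of probe sets and 1618 without _x_at and _s_at probe sets, where 17098 of 19775 genes could be tested, and 26 and 63 genes were called in the opposite direction. Genes such as CD24, EPCAM and MYC had only _x_at or _s_at probe sets and could not be tested without them. The mean of probe sets turned NANOG to -0.0085 and CD44 to 0.14, LIN28B was 0.0074 without PC-3/S replicate 1 and otherwise down to -0.10 with 1 array left out, and without _x_at and _s_at probe sets FN1 was 0.18 and MAGEC2 -0.15. The GAPDH 3' difference was -0.018 with the middle probe set, against -0.073. The planned change of pseudocount was not run, since the values were already log2.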

Other observations

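The leukocyte, scaling, random-order and copy-number tests below, and the gene families, interferon receptor genes and CTNNA1 looked at, were chosen only after the results were seen; the regional subtraction, cross-hybridisation and array-bias tests were planned before.

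Zinc finger genes named ZNF were lower in PC-3/Mc as a family (median -0.25 over 241 genes, and -0.33 or -0.20 with quantile-normalized or centred arrays), 119 lower and 44 higher, at a camera adjusted p of 0.0011 over 57 families. The 90 on chromosome 19 had a median of -0.43 (-0.48 or -0.38 with rescaled arrays), with 59 lower and 7 higher. The 151 elsewhere had a median of -0.09 (-0.14 or -0.05), with 60 lower and 37 higher. The difference between these groups was not tested. Chromosome 19 also held low windows of neighbouring genes, such as FCGRT to ZNF320 (median -0.78, 29 of 40 genes lower). A shift of the family there cannot be told apart from a regional one. Mitochondrial ribosomal protein genes named MRPL were higher (median 0.36 over 49 genes, 0.28 or 0.41 with rescaled arrays), 31 higher and 3 lower, at an adjusted p of 0.0127. Both family calls were lost with an estimated correlation (adjusted p = 0.987).

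Interferon receptor genes IFNAR1 (-1.17), IFNAR2 (-1.18) and IL10RB (-1.46), neighbours on chromosome 21, were lower in PC-3/Mc. That chromosome also held the lowest window of neighbouring genes described below, MIS18A to MX1 (median -1.04, 34 of 40 genes lower). The receptor differences were of similar size, so they cannot be told apart from a regional shift. IFNGR2, beside them, differed by -0.22 at an adjusted p of 0.046, and IFNGR1, on another chromosome, was higher at 0.87. The transcription factor genes IRF1 (-2.24) and IRF9 (-2.14) were lower as well. CTNNA1, which encodes alpha-catenin and is known to be deleted in PC-3, was at 3.51 to 5.18 on its 5 probe sets in all arrays, against a median of 5.05 for all probe sets.

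The interferon, antigen presentation and cytokine lists, lower in PC-3/Mc, could come from white blood cell RNA in the PC-3/S cultures, from array scaling, from regional differences, or from a lower inflammatory state of the cells. White blood cells would bring their own markers along, but 14 such markers outside the lists had a median of -0.078 (SD 0.28). The list medians were -1.65, -0.42 and -1.43. LCP1 was lowest at -0.79, and PTPRC was at 0.18. These values argue against the first, although LCP1 alone moved more than the antigen presentation median. A test on the lowest marker, tried before this one, left that list open. Most of the markers read under 5.18 in both lines, so a small amount of such RNA would not be seen. Ribosomal protein genes had a median of -0.04 (-0.0427), far smaller than the list shifts, which argues against a shift of whole arrays. Their median level in PC-3/Mc was 13.21, against 5.47, 6.53 and 5.30 for the lists. A scaling error that depends on brightness is therefore not covered. Subtraction of the differences of neighbouring genes could be run on bright, placed members only: over 28 of 44, 11 of 21 and 18 of 34 the medians moved from -1.73 to -1.68, -1.05 to -0.84 and -1.96 to -2.12, with a largest adjusted p of 0.0124, which argues against regional differences as the whole cause among these members at the preset correlation; the list calls themselves are lost with an estimated one (0.201, 0.185 and 0.155), and that of antigen presentation without _x_at and _s_at probe sets (0.42). A state of the cells stays possible, as does a batch that went with the line, but no interferon or cytokine protein was measured.

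Neighbouring genes differed together: the rank correlation of the differences of adjacent genes was 0.245 over 9872 genes, above all 10000 random orders (largest 0.038, p = 1e-04, the smallest these orders can give). Only bright, placed genes entered, 9872 of 19775. Neighbours here and in the windows below are therefore those left after dimmer genes were dropped. Cross-hybridisation between related neighbours would leave little once pairs of similar name and probe sets ending in _x_at or _s_at are removed, yet the correlation was 0.190 over 8120 genes. Array bias that follows the genome, such as GC content, could also give it: differences between arrays of the same line reached 0.302 (PC-3/Mc 2 minus PC-3/Mc 3), above the value between the lines. The correlation alone therefore cannot separate biology from bias.

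Of 908 overlapping windows of 40 neighbouring genes, 28 lay beyond random orders, 19 lower and 9 higher in PC-3/Mc. Window medians of random orders ran from -0.54 to 0.76, so a lower window needed a smaller shift to be counted. The lowest, MIS18A to MX1 on chromosome 21, had a median of -1.04 (-1.13 or -0.99 with rescaled arrays) with 34 of 40 genes lower, and the highest, HTT to LCORL on chromosome 4, 0.86 (0.81 or 0.91). Array bias reached a window median of only 0.261 between arrays of the same line, which argues against bias of single arrays as the source. Bias shared by all arrays of a line cancels in these differences, so it is not covered. Different copy number could give such windows, as could regional regulation or a batch that went with the line, and no DNA was measured. The regional subtraction took the median of the hypoxia list, over 31 of 33 members, from 0.45 to 0.21 (47.6% kept) and its adjusted p from 0.0448 to 0.165.

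Of the 10 ways to divide the arrays into 3 and 3, the real one gave 9083 genes, 2266 of at least 2-fold and 9 lists, and the highest other gave 0, 0 and 7. The real division ranked 1 for each count, but 10 divisions cannot give a share under 0.05. Every other division put arrays of both lines in both groups. The line difference then adds to the spread within groups, which holds the gene counts down, and part of it remains between groups. The counts of those divisions are therefore no measure of chance.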
